A study of Homo sapiens with 6 samples.

How the data were processed

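The data are RNA sequencing of total RNA from 6 libraries labelled MCF-7, 3 control and 3 treated with corticosterone, as the labels give them. Neither dose, duration nor culture conditions are given in the sources used here. The extraction text of the labels names both a column kit and a phenol reagent, with 1.3 ug of total RNA per library. The submitters' processing notes name the genome build GRCh38, while the aligner, counter, annotation release and filters are not given in the sources used here. The deposited table holds a whole-number count per gene and library and, per the file headers, an FPKM value made by the authors, which scales fragments by gene length and depth. Counts were used as deposited, and FPKM only in an alternative. The length implied by count and FPKM differed between libraries by a median of 1.09% over 11740 genes with at least 200 counts.

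Total counts were 52294975, 52539873 and 82118974 in control 1, 2 and 3, and 81802183, 56709506 and 56973622 in corticosterone 1, 2 and 3. A count of 4 occurred 8335 times and a count of 3 only 5496 times, and 8 (3383) exceeded both 7 (2791) and 9 (1957). By this 1 fragment seems to add several counts and the totals overstate the depth. A floor of 3 counts corresponds to between 0.0365 and 0.0569 CPM, and it covers counting error only. Mitochondrial genes took 7.68% to 9.39% of counts and the 10 most abundant genes 8.06% to 9.26%. The table holds 36271 genes, of which 34379 matched GENCODE release 29 by identifier, 34363 of them at an overlapping position, and 36235 matched the table of gene names. No library duplicated another, with a chi-square per degree of freedom of at least 11.8 between libraries of 1 group, or 2.96 with counts divided by 4.

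Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr by group and the quasi-likelihood test of corticosterone against control, on 19951 genes. The adjustment was Benjamini-Hochberg over the genes tested with a threshold of 0.05, and a second count also asked for an absolute log2 fold change of at least 1. CPM values use TMM-scaled library sizes and have no added pseudocount. The log2 fold change of a gene without counts in a group depends on the prior count, so in the main fit it is given as a bound. On simulated data with the same size and 19951 genes, edgeR recovered 73.1% of 67 genes changed 1.5-fold, 86.6% of 67 changed 2-fold and 100.0% of 66 changed 4-fold, with 4 false calls (2.26%). DESeq2 1.42.0 recovered 79.1%, 92.5% and 100.0% with 39 false calls (17.7%), and limma 3.58.1 recovered 71.6%, 86.6% and 100.0% with 5 (2.82%). Every changed gene in that simulation had an average log2 CPM over 1, and every gene had the dispersion of the fitted trend. Few genes were changed, and repeated counting of a fragment was not included. These shares need not hold for genes of low counts or for data with many changes.

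A total of 37 gene lists were written from general knowledge before the data were examined, and each had at least 5 tested members. They cover glucocorticoid, oestrogen, androgen or progesterone receptor and LXR targets, steroid receptors and enzymes, cell cycle, p53, apoptosis, stress responses, lipid and energy metabolism, ribosome, histones, interferon, inflammation, antigen presentation, metallothioneins, ion transport, clock, immediate early genes, autophagy, transition and stemness, and markers of luminal, basal, fibroblast, immune and endothelial cells. None was chosen on these samples. Lists were tested with camera of limma, two-sided, at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg over the 37 lists, beside camera with an estimated correlation and fry. With an estimated correlation only the glucocorticoid receptor targets passed, and with fry 12 lists. KEGG terms of 10 to 500 members were tested with Fisher's exact test on called genes against tested genes in any term, with scipy 1.17.1 and pandas 2.3.3 under Python 3.11.15.

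The rule for named genes was also set before the data were examined. It took symbols with an adjusted p below 0.05, the 3 libraries of each group apart from those of the other, and a mean of at least 20 counts in the higher group. From these came the 8 with the largest log2 fold change in each direction and the 8 with the smallest p in each direction. It added up to 4 members of each list, the 2 past the threshold with the smallest p in each direction, or the 2 most abundant where none passed, and a fixed set with the steroid receptors and their classical targets. It gave 115 tested genes, of which 96 passed, each with the 3 libraries of each group apart, and 45 of these passed in every fit that left out 1 library.

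Alternatives set beforehand were DESeq2, limma-trend, limma-voom, DESeq2 size factors in edgeR, library size only, no filter, at least 50 counts in 3 libraries, and limma on log2(FPKM + 1) for genes with at least 1 FPKM in 3 libraries. Others were the replicate number as a block, protein-coding genes only, an adjusted p below 0.01, and leaving out each library in turn. Another 5 were chosen after seeing the data. The fit without control 1 and 2 assumes that the lone control varies like the other libraries. The remaining 4 were a term for the 3 pairs of libraries alike in total count, leaving out 639 genes more than 2-fold higher in control 1 and 2 than in control 3, counts divided by 4, and a correction of the trend with gene length. The pairs alike in total count are control 1 and 2, control 3 and corticosterone 1, and corticosterone 2 and 3, so only 1 pair holds both groups. Gene length correlated with log2 fold change across 13391 genes with a Spearman rho of 0.177. Lists of 31 placental and 22 small structured RNA genes were also written after the values were seen. Sex-linked expression was not examined.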

Results

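RNA sequencing was analysed in 6 libraries labelled MCF-7, an established human breast cancer cell line that is classically luminal and positive for the oestrogen receptor. Of these, 3 came from control cells and 3 from cells treated with corticosterone, a steroid hormone that binds the glucocorticoid and mineralocorticoid receptors. Neither the dose nor the duration is given in the sources used here. Total counts were 52294975, 52539873 and 82118974 in control 1, 2 and 3, and 81802183, 56709506 and 56973622 in corticosterone 1, 2 and 3. Log2 counts scaled to library size (CPM) were compared over at least 13391 genes with an average log2 CPM over 1. These genes are not independent replicates. Pearson r was 0.967 to 0.983 between controls and 0.980 to 0.986 between corticosterone libraries. The labels do not say that the 3 samples of a group were separate cultures, so p-values of single genes measure the spread between these samples. Camera at its preset correlation compares list members with other genes, and the Fisher's exact tests of KEGG terms and markers count genes. Their p-values therefore rest on genes, which are not independent. All positions are on GRCh38, group values are means ± SD of CPM with n = 3, and log2 changes are corticosterone minus control ± SE.

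The comparison of the groups asks which transcripts differ after corticosterone. Treated cells held more RNA of hallmark glucocorticoid receptor targets, among them FKBP5, PER1, TSC22D3 and SCNN1A, and less of several interferon-stimulated genes, among them OASL and ISG15, and of SOCS3. FKBP5, a co-chaperone of steroid receptors, rose from 48.0 ± 3.87 to 243 ± 3.99 CPM, and OASL, an interferon-induced antiviral protein, fell from 144 ± 10.8 to 63.1 ± 0.716 CPM. The matrix proteoglycan DCN rose from 9.97 ± 1.77 to 94.9 ± 2.49 CPM. Genes of ribosomal proteins and of nuclear oxidative phosphorylation held no member past the threshold.

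Of 19951 genes tested with edgeR, 1038 passed the Benjamini-Hochberg threshold, 541 higher and 497 lower with corticosterone. Of these, 157 also changed at least 2-fold, 84 higher and 73 lower. The 3 libraries of each group lay apart from those of the other in 5037 genes (25.3%), and in 1032 of the 1038, where a small p favours such genes. Chance gives 10% for a gene whose 6 libraries are interchangeable. Genes are not independent and the share was not counted for other splits, so the excess cannot be credited to the treatment. The number of genes called was 379 without control 1, 565 without control 2 and 2513 without control 3. It was 379 without corticosterone 1, 304 without corticosterone 2 and 554 without corticosterone 3, and DESeq2 called 1975 genes. Counts of calls within many gene lists also moved with the library left out. Control 1 and 2 also held placental and small structured RNAs that the other 4 libraries nearly lacked, and a fit without both called 281 genes, 187 higher and 94 lower.

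**Figure D1:**
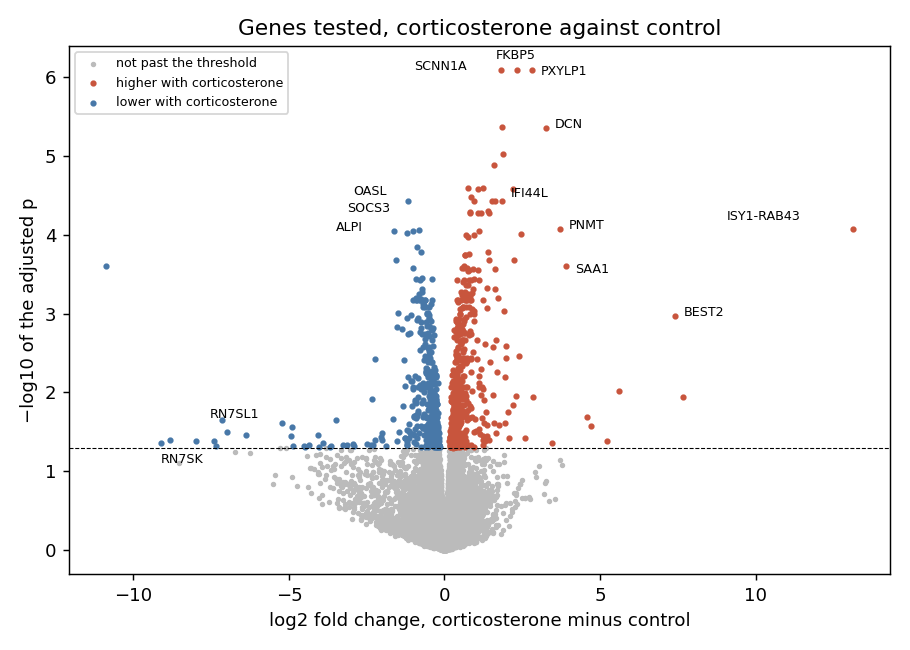
Each point is 1 of the 19951 genes tested, by its log2 fold change (corticosterone minus control) and the negative log10 of its edgeR adjusted p; coloured points passed the threshold, drawn as a dashed line. FKBP5, SCNN1A and PXYLP1 had the smallest adjusted p, 8.2e-07.

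The strongest rises by p-value were in PXYLP1, SCNN1A and FKBP5, each with an edgeR adjusted p of 8.2e-07. PXYLP1 (ENSG00000155893, chromosome 3, 141228726 to 141321722, plus strand), a phosphatase of the proteoglycan linker, rose from 5.04 ± 0.251 to 35.4 ± 0.673 CPM, a log2 change of 2.81 ± 0.07. SCNN1A (ENSG00000111319, chromosome 12, 6346843 to 6377730, minus strand), the alpha subunit of the epithelial sodium channel, rose from 58.1 ± 0.661 to 205 ± 8.34 CPM, a log2 change of 1.82 ± 0.05. FKBP5 (ENSG00000096060, chromosome 6, 35573585 to 35728583, minus strand) had a log2 change of 2.34 ± 0.06. PER1 (ENSG00000179094, chromosome 17, 8140472 to 8156405, minus strand), a repressor of the circadian clock, rose from 38.4 ± 2.89 to 137 ± 1.37 CPM (edgeR adjusted p = 4.3e-06). ABLIM3, an actin-binding protein, had a log2 change of 1.58 ± 0.07 (edgeR adjusted p = 1.3e-05), and the complement component C3 rose from 375 ± 2.52 to 626 ± 11.6 CPM (edgeR adjusted p = 2.6e-05). INHA, the inhibin alpha subunit, went from 17.7 ± 1.28 to 64.4 ± 3.95 CPM (edgeR adjusted p = 9.4e-06), but OBSL1, which overlaps it on the other strand, went from 193 to 341 CPM.

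The rises of largest fold included DCN (ENSG00000011465, chromosome 12, 91140484 to 91182817, minus strand), with a log2 change of 3.25 ± 0.12 (edgeR adjusted p = 4.5e-06). BEST2, a bicarbonate-permeable anion channel, rose from 0.0948 ± 0.164 to 14.3 ± 0.959 CPM (edgeR adjusted p = 0.0011). Its control counts all came from control 1, at 0.284 CPM, so the size of its log2 change of 7.40 is uncertain, from 6.64 without control 3 to 12.88 without control 1. SAA1, an acute-phase apolipoprotein, rose from 0.261 ± 0.0962 to 3.97 ± 0.305 CPM (edgeR adjusted p = 0.00025). PNMT, the adrenaline-forming enzyme, rose from 0.301 ± 0.0489 to 3.98 ± 0.467 CPM (edgeR adjusted p = 8.4e-05). GMPR went from 0.252 to 5.69 CPM (edgeR adjusted p = 0.021). That call was lost without control 1 or any corticosterone library, with adjusted p up to 0.13. GMPR was at 0.152 and 0.604 CPM in control 1 and 2 and had no counts in control 3. Its log2 change of 4.58 was 11.6 without both control 1 and 2, a size that depends on the prior count. The read-through gene ISY1-RAB43 had no counts in the controls and 17.7 ± 4.83 CPM with corticosterone (edgeR adjusted p = 8.4e-05). Against a floor of 3 counts per library it was at least 353-fold higher. That bound would be lower where 1 fragment adds several counts. RAB43, which overlaps ISY1-RAB43, went from 27.2 to 16.1 CPM. The sum of ISY1-RAB43, RAB43 and ISY1 was 82.0 ± 2.86 CPM in controls and 84.2 ± 3.31 CPM with corticosterone. Counts of C1QTNF3-AMACR (edgeR adjusted p = 0.027) and CCDC39 (edgeR adjusted p = 0.044) also lay in overlapping gene models. The sum of C1QTNF3-AMACR and C1QTNF3 went from 5.03 to 8.03 CPM, and that with AMACR from 30.8 to 32.7 CPM. ENSG00000145075, on the strand of CCDC39, went from 3.66 to 0 CPM, and its sum with CCDC39 fell from 3.87 to 2.58 CPM. The calls of C1QTNF3-AMACR and CCDC39 were lost without control 1 or 2 or any corticosterone library, with adjusted p up to 0.13 and 0.21.

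Among falls, OASL (ENSG00000135114, chromosome 12, 121017763 to 121039246, minus strand) had the smallest p, with a log2 change of -1.19 ± 0.06 (edgeR adjusted p = 3.7e-05). SOCS3, a feedback inhibitor of cytokine signalling, fell from 65.2 ± 1.01 to 37.1 ± 1.09 CPM (edgeR adjusted p = 8.7e-05), and ISG15, a ubiquitin-like antiviral modifier, fell from 80.2 ± 5.18 to 39.9 ± 1.59 CPM (edgeR adjusted p = 9.0e-05). The intestinal alkaline phosphatase ALPI had a log2 change of -1.62 ± 0.10 (edgeR adjusted p = 9.0e-05), the carboxypeptidase CPA4 of -1.21 ± 0.08 (edgeR adjusted p = 9.5e-05) and IGFN1 of -1.57 ± 0.12 (edgeR adjusted p = 0.00021). MFSD12, a lysosomal cysteine transporter, went from 398 to 236 CPM (edgeR adjusted p = 0.00016), and HMG20B, which overlaps it on the other strand, from 284 to 210 CPM. DNAH17-AS1 went from 54.6 to 29.5 CPM (edgeR adjusted p = 0.00014), and DNAH17 on the other strand from 49.3 to 31.4 CPM.

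The falls of largest fold were in transcripts at their highest in control 1 and 2. RN7SL1, RN7SL2, RN7SL4P and RN7SL5P, genes and pseudogenes of the signal recognition particle RNA, and RN7SK, a small RNA that restrains transcription elongation, had log2 changes between -8.84 and -6.39 with edgeR adjusted p between 0.032 and 0.042. RN7SL1 was 288 ± 260 CPM in the controls and 2.23 ± 0.753 CPM with corticosterone. The placental glycoprotein PSG1 (edgeR adjusted p = 0.048) and the leukocyte genes IRF8 (edgeR adjusted p = 0.024) and HLA-DQB1 (edgeR adjusted p = 0.036) fell as well, by log2 changes of -4.88, -5.21 and -4.93. With 1 library left out these ran from -5.43 to -3.19, from -8.20 to -4.77 and from -8.16 to -4.24. All 8 calls were lost without control 1, control 2, corticosterone 1 or corticosterone 2, and all but that of HLA-DQB1 without corticosterone 3, with the largest adjusted p of each between 0.13 and 0.21. Without both control 1 and 2, their adjusted p lay between 0.58 and 0.97. The log2 changes were then between -1.46 and -0.40 in the small RNAs and PSG1, and -3.74 and -3.67 in IRF8 and HLA-DQB1.

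**Figure D2:**
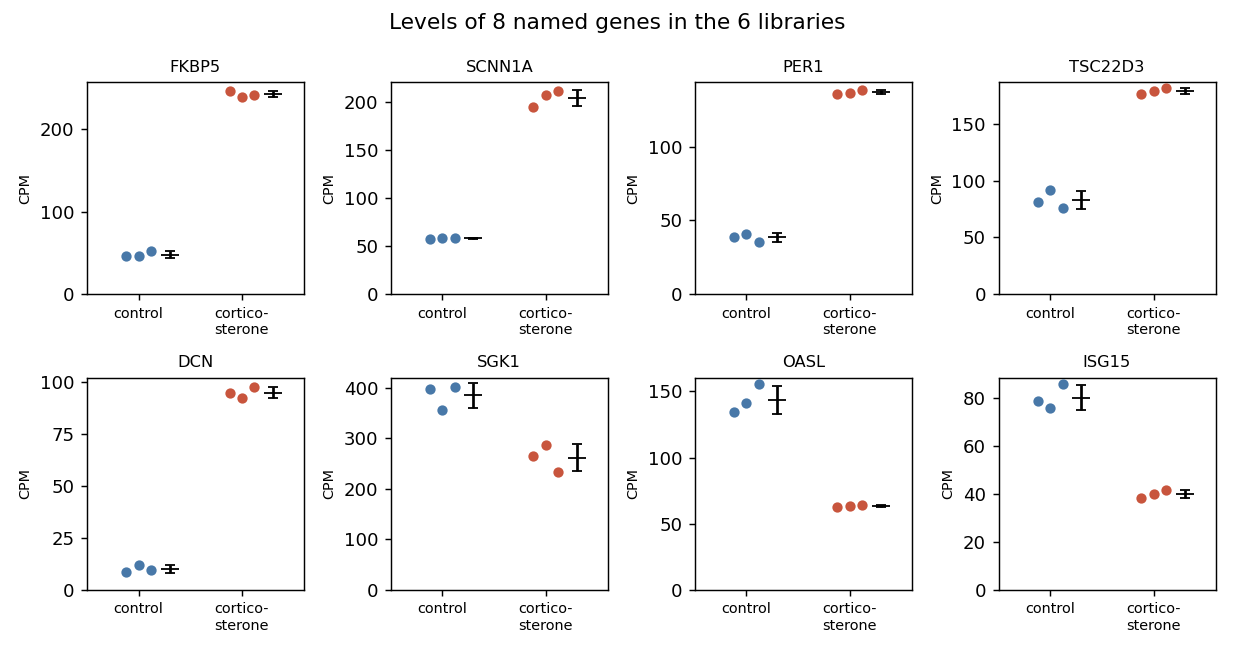
CPM on a linear axis from 0 for 8 genes named in the text; points are the 3 libraries of each group, and the black marks beside them are the group mean ± SD. FKBP5 went from 48.0 to 243 CPM and OASL from 144 to 63.1 CPM.

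Glucocorticoid receptor targets, genes that the ligand-bound receptor induces in many cell types, rose as a list. Of 38 tested, 22 rose, 1 fell and 15 did not pass, with 23 higher and 3 lower adjusted over the list alone, and a median log2 change of 0.56. TSC22D3, also called GILZ, rose from 82.9 ± 8.14 to 179 ± 2.39 CPM (edgeR adjusted p = 9.0e-05), the apoptosis inhibitor BIRC3 from 26.1 ± 4.45 to 80.2 ± 7.86 CPM, and the phosphatase DUSP1 from 214 ± 7.19 to 334 ± 16.4 CPM. The member that fell was SGK1, a kinase that glucocorticoids induce in many cells, from 386 ± 25.01 to 262 ± 26.1 CPM (log2 change -0.56 ± 0.08, edgeR adjusted p = 0.0051). ZBTB16 stayed below 1 CPM on average in both groups (edgeR adjusted p = 0.44), and KLF9 had a log2 change of 0.39 (edgeR adjusted p = 0.028), with adjusted p up to 0.16 in the fits without control 1, control 2, corticosterone 1 or corticosterone 2. In camera the list had an adjusted p of 6.5e-71, and 0.0011 with an estimated correlation. Without both control 1 and 2, 19 members passed higher and 1 lower, and with the pairs of like library size as a term 17 passed higher and 0 lower. SGK1 kept its fall there, with a log2 change of -0.60, at an adjusted p of 0.11.

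The receptors themselves gave few calls. NR3C1, the glucocorticoid receptor, was at 93.1 ± 6.05 CPM in controls and 101 ± 3.73 CPM with corticosterone (edgeR adjusted p = 0.31), and the mineralocorticoid receptor NR3C2 was at 0.821 ± 0.0919 and 0.664 ± 0.204 CPM (edgeR adjusted p = 0.65). ESR1, the oestrogen receptor, was at 0.808 ± 0.293 and 2.19 ± 1.72 CPM (edgeR adjusted p = 0.17). Its treated mean rested on corticosterone 1, at 4.16 CPM against 1.40 and 1.003 CPM in corticosterone 2 and 3, and its log2 change of 1.43 was 0.56 without that library. The androgen receptor AR was at 0.428 and 0.105 CPM (edgeR adjusted p = 0.56), with no counts in control 3, corticosterone 2 and corticosterone 3. Its log2 change of -1.86 ranged from -7.67 to -0.53 with 1 library left out and was 5.95 without both control 1 and 2. The size of 5.95 depends on the prior count, since control 3 had no counts, as does that of a fit without corticosterone 1. The progesterone receptor PGR was not tested, with 4.28 CPM in corticosterone 1 and at most 0.170 CPM in any other library. Of 6 steroid receptors tested, only the membrane oestrogen receptor GPER1 passed, lower (log2 change -0.58, edgeR adjusted p = 0.0058, and -0.66 and 0.059 without both control 1 and 2), with 0 higher and 1 lower adjusted over the list alone and a camera adjusted p of 0.71.

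Oestrogen receptor targets went both ways, with 3 of 23 higher and 4 lower, 3 and 8 adjusted over the list alone, and a camera adjusted p of 0.053. Their camera adjusted p was as low as 0.034 in the fits without control 1 or corticosterone 2. GREB1 was at 5.20 ± 1.12 and 4.91 ± 0.187 CPM (edgeR adjusted p = 0.83), and TFF1 was at most 0.151 CPM in any library. MYC, the growth-related transcription factor, fell by 0.29 on the log2 scale (edgeR adjusted p = 0.013), and PDZK1, NRIP1 and ADORA1 also passed, the first 2 higher. MYC lost its call without control 1, corticosterone 1 or 3 (adjusted p up to 0.086), and PDZK1 without any library but control 3 (up to 0.080). NRIP1 lost it without control 1, control 2, corticosterone 1 or 2 (up to 0.15), and ADORA1 without control 1 or any corticosterone library (up to 0.13). Androgen or progesterone receptor targets had 2 of 8 higher and 0 lower, 3 and 1 adjusted over the list alone, and passed upward in camera (adjusted p = 1.7e-07, adjusted p = 0.094 with an estimated correlation). The median log2 change of that list was 0.07, with 4 members positive and 4 negative, and FKBP5 belongs to it as well. Steroid and bile acid enzymes had 4 of 16 higher and 0 lower, 6 and 2 adjusted over the list alone. Their median log2 change was 0.07, their mean -0.38 and their upward camera adjusted p 0.053, which was 0.036 without control 1 and 0.0051 without both control 1 and 2. AKR1C1 and AKR1C2, reductases that inactivate steroids, rose by log2 changes of 0.58 and 0.86 (edgeR adjusted p = 0.0040 and 0.0036), with adjusted p of 0.032 and 0.079 and log2 changes of 0.66 and 0.88 without both control 1 and 2.

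Interferon-stimulated genes fell as a list. Of 24 tested, 7 fell, 1 rose and 16 did not pass, with 10 lower and 1 higher adjusted over the list alone. The median log2 change was -0.23 and the camera adjusted p 2.8e-05 (adjusted p = 0.30 with an estimated correlation). OASL and ISG15 fell, while IFI44L, another interferon-induced gene, rose from 5.40 ± 0.432 to 19.6 ± 0.816 CPM (edgeR adjusted p = 3.7e-05). Without both control 1 and 2, 7 members still passed lower and 1 higher, and 4, 3, 2 and 4 passed lower without control 1, corticosterone 1, corticosterone 2 and corticosterone 3. Antigen presentation genes fell in camera (adjusted p = 0.00042, adjusted p = 0.31 with an estimated correlation), with 3 of 15 lower and 0 higher, 5 and 0 adjusted over the list alone. HLA-B, a class I heavy chain, fell by 0.34 on the log2 scale (edgeR adjusted p = 0.0048) and its transactivator NLRC5 by 0.28 (edgeR adjusted p = 0.012). In the fit without both control 1 and 2, 0 members passed and their adjusted p were 0.10 and 0.15, while both log2 changes were -0.28 and the camera adjusted p of the list was 0.0051. In the fits without control 1, control 2, corticosterone 1, 2 and 3, 1, 2, 1, 1 and 2 members passed, and that of NLRC5 was up to 0.081 in the fits without control 1, corticosterone 1 or corticosterone 2.

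NF-kB and inflammatory genes had 4 of 23 lower and 1 higher, 7 and 2 adjusted over the list alone, with a camera adjusted p of 0.067, and 0.013 without control 3, where 8 passed lower. The cytokine IL6 went from 12.03 ± 2.35 to 6.26 ± 0.638 CPM (edgeR adjusted p = 0.013) and PTGS2, the inducible cyclooxygenase, from 12.6 ± 2.18 to 6.51 ± 1.01 CPM (edgeR adjusted p = 0.013). The calls of both were lost without corticosterone 2 or 3, and that of IL6 without control 1, with adjusted p up to 0.097 for IL6 and 0.10 for PTGS2. BIRC3 was the member that rose. Immediate early genes, which respond first to growth signals and stress, fell in camera (adjusted p = 0.00042, adjusted p = 0.39 with an estimated correlation), with 7 of 24 lower and 3 higher, 12 and 3 adjusted over the list alone. NR4A1 fell from 67.8 ± 2.50 to 40.3 ± 3.34 CPM (edgeR adjusted p = 0.00065) and IER3 from 106 ± 4.85 to 72.2 ± 3.23 CPM (edgeR adjusted p = 0.0010), while KLF6 (edgeR adjusted p = 0.00017) and DUSP1 (edgeR adjusted p = 0.00027) rose by log2 changes of 0.79 and 0.64. Without both control 1 and 2, 2 members passed lower and 2 higher, the median moved from -0.34 to -0.10 and the camera adjusted p was 0.19. Leaving out control 1, control 3, corticosterone 1, 2 and 3 gave 3, 15, 3, 4 and 4 members past the threshold downward.

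Heat shock genes fell in camera (adjusted p = 1.7e-07, adjusted p = 0.11 with an estimated correlation), with 7 of 16 lower and 0 higher, 11 and 0 adjusted over the list alone, and a negative log2 change in all 16. HSPA1A, an inducible chaperone, fell by 0.42 on the log2 scale (edgeR adjusted p = 0.014) and its constitutive relative HSPA8 by 0.22 (edgeR adjusted p = 0.014). No member passed without both control 1 and 2, without corticosterone 1 or without corticosterone 2, and 1, 2, 9 and 4 passed without control 1, control 2, control 3 and corticosterone 3. The log2 changes of HSPA1A and HSPA8 were -0.25 and -0.24 without both control 1 and 2, where the list still fell in camera (adjusted p = 9.4e-08). HSPA1A had an adjusted p up to 0.097 without control 1, corticosterone 1 or 2, and HSPA8 up to 0.11 without corticosterone 1 or 2. Clock genes split, with 7 of 17 lower and 2 higher, 10 and 2 adjusted over the list alone, and a camera adjusted p of 0.16. Without corticosterone 2, 3 passed lower. PER1 and ARNTL rose, while the repressors CRY1 (log2 change -0.52, edgeR adjusted p = 0.0028) and BHLHE40 (log2 change -0.39, edgeR adjusted p = 0.0016) fell. CRY1, BHLHE40 and ARNTL had adjusted p of 0.086, 0.051 and 0.30 without both control 1 and 2, with log2 changes of -0.50, -0.37 and 0.30. ARNTL, with a log2 change of 0.44 and an adjusted p of 0.018 in edgeR, had up to 0.10 when any library but control 3 was left out.

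Genes of the G1/S transition and DNA replication rose in camera (adjusted p = 3.3e-05, adjusted p = 0.11 with an estimated correlation), with 3 of 26 higher and 0 lower, 13 and 0 adjusted over the list alone, and a median log2 change of 0.12. RRM2, a subunit of ribonucleotide reductase, rose from 311 ± 11.2 to 381 ± 8.05 CPM (edgeR adjusted p = 0.0060) and CCNE2, cyclin E2, from 25.9 ± 0.685 to 38.4 ± 4.67 CPM (edgeR adjusted p = 0.0085). Their log2 changes were 0.29 and 0.57. Without both control 1 and 2, 0 members passed and their adjusted p were 0.10 and 0.18, while their log2 changes were 0.27 and 0.54 and the list still rose in camera (adjusted p = 9.4e-05). RRM2 had 0.052 without corticosterone 2, CCNE2 up to 0.056 without control 1 or corticosterone 1, and 1, 2, 8, 1 and 1 members passed without control 1, control 2, control 3, corticosterone 1 and corticosterone 2. No gene of the G2/M and mitosis list passed over all genes or over the list alone (0 of 26 in edgeR, camera adjusted p = 0.21), while 6 were higher and 2 lower at an unadjusted p under 0.05 and DESeq2 called 4 higher and 1 lower. Its camera adjusted p was 0.0051 without control 3. The proliferation marker MKI67 was at 423 ± 22.3 and 472 ± 8.93 CPM (edgeR adjusted p = 0.094), and TOP2A (edgeR adjusted p = 0.18) and TPX2 (edgeR adjusted p = 0.48) did not pass.

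p53 targets fell in camera (adjusted p = 0.023, adjusted p = 0.37 with an estimated correlation), with 4 of 21 lower and 0 higher over all genes, and 4 and 0 adjusted over the list alone. GDF15, a stress-induced cytokine, fell from 73.0 ± 8.02 to 48.6 ± 2.05 CPM (log2 change -0.59, edgeR adjusted p = 0.0054). Its log2 change was -0.41 and its adjusted p 0.062 without both control 1 and 2. The list had an adjusted p up to 0.058 without corticosterone 1 or 3, and 0.19 without both control 1 and 2. Apoptosis regulators had 5 of 22 higher and 2 lower, 6 and 2 adjusted over the list alone, and passed upward in camera (adjusted p = 0.042, adjusted p = 0.30 with an estimated correlation) beside a median log2 change of 0.00094. The list's adjusted p was 0.058 without corticosterone 3, 0.052 with library size only, 0.072 with at least 50 counts in 3 libraries and 0.071 over protein-coding genes only. BIRC3, which inhibits cell death, rose. BMF, which promotes it, also rose (log2 change 0.58, edgeR adjusted p = 0.0085, up to 0.059 without control 1 or corticosterone 2).

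Metallothionein and zinc genes passed upward in camera (adjusted p = 0.013, adjusted p = 0.31 with an estimated correlation), with 2 of 6 higher and 0 lower, 2 and 1 adjusted over the list alone. MT2A, a metal-binding protein, rose from 106 ± 9.12 to 183 ± 14.3 CPM (edgeR adjusted p = 0.00084) and MT1E from 17.7 ± 1.66 to 31.7 ± 2.23 CPM (edgeR adjusted p = 0.0010). The list's adjusted p was up to 0.10 without control 2, control 3 or corticosterone 3. Ion and sodium transport genes passed upward in camera (adjusted p = 0.022, adjusted p = 0.30 with an estimated correlation, adjusted p = 0.060 without control 3), although their median log2 change was -0.11 and their mean -0.01. In that list 1 of 11 was higher, SCNN1A, and 0 lower, with 2 and 3 adjusted over the list alone.

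**Figure D3:**
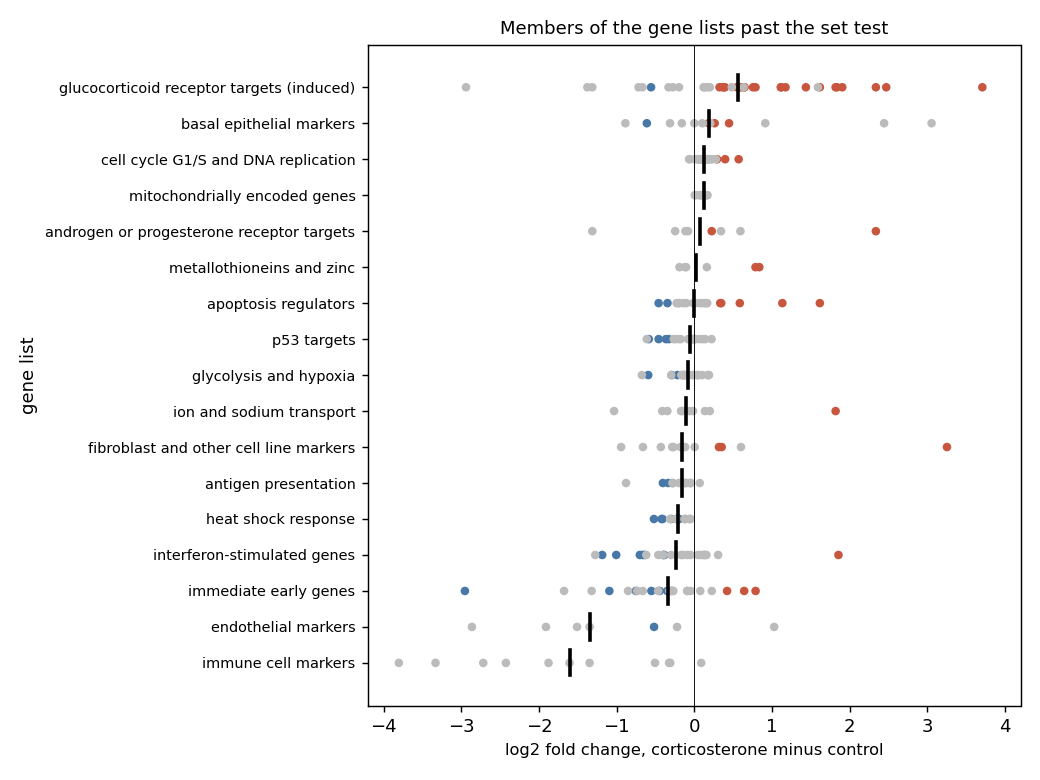
Log2 fold change (corticosterone minus control) of each tested member of the 17 gene lists past the camera threshold; red and blue points rose and fell in edgeR, grey points did not pass, and black bars are list medians. Glucocorticoid receptor targets had a median of 0.56 and immune cell markers one of -1.61.

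In metabolism, glycolysis and hypoxia genes fell in camera (adjusted p = 0.022, adjusted p = 0.39 with an estimated correlation), with 3 of 25 lower and 0 higher, 5 and 0 adjusted over the list alone. The glucose transporter SLC2A1 fell by 0.29 on the log2 scale (edgeR adjusted p = 0.018, up to 0.097 without control 1, control 2, corticosterone 1 or 2). The list's adjusted p was 0.071 without corticosterone 1 and 0.083 without both control 1 and 2. Genes encoded by mitochondrial DNA passed upward in camera (adjusted p = 0.024, adjusted p = 0.52 with an estimated correlation, adjusted p = 0.18 without corticosterone 3), with 0 of 13 past the threshold in edgeR over all genes or over the list alone. At an unadjusted p under 0.05, 3 were higher, DESeq2 called 2, and the camera adjusted p was 0.48 without both control 1 and 2. Among them MT-CO1 was at 18584 ± 1660 and 20616 ± 859.5 CPM (edgeR adjusted p = 0.21). Fatty acid and lipid storage genes had 2 of 19 higher and 2 lower, 3 and 3 adjusted over the list alone, and a downward camera adjusted p of 0.93 beside a median log2 change of 0.03. FASN, the fatty acid synthase, fell by 0.21 on the log2 scale (edgeR adjusted p = 0.0076) and its regulator SREBF1 by 0.32 (edgeR adjusted p = 0.0061). FASN had up to 0.069 without control 1, corticosterone 1 or 2, and SREBF1 0.063 without corticosterone 2. LPIN1 rose by a log2 change of 0.36 (edgeR adjusted p = 0.015, up to 0.12 without control 1 or any corticosterone library). Cholesterol genes had 2 of 24 higher and 0 lower, 3 and 0 adjusted over the list alone (camera adjusted p = 0.15). DHCR24, the last enzyme of a synthesis branch, rose by a log2 change of 0.22 (edgeR adjusted p = 0.0085, up to 0.067 without control 1, corticosterone 1 or 2). LXR targets had 0 of 9 higher and 1 lower, 0 and 3 adjusted over the list alone, with a camera adjusted p of 0.069, and 0.036 without control 1.

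In stress and housekeeping groups, ATF4 amino acid response genes had 3 of 23 higher and 2 lower, 6 and 6 adjusted over the list alone (camera adjusted p = 0.62), with ALDH1L2 higher and the amino acid transporter SLC7A5 lower. ALDH1L2 had an adjusted p up to 0.073 without control 1 or corticosterone 2, and SLC7A5 up to 0.13 without any library but control 3. The upward camera adjusted p of that list, beside a median log2 change of 0.05 and a mean of -0.01, was 0.017 without both control 1 and 2. Unfolded protein response genes had 1 of 20 higher and 1 lower, 1 and 2 adjusted over the list alone (camera adjusted p = 0.62). NRF2 and oxidative stress genes had 3 of 21 higher and 2 lower, 5 and 7 adjusted over the list alone (downward camera adjusted p = 0.93), with a median log2 change of -0.02 and a mean of 0.04. In that list FTL, the ferritin light chain, fell from 1696 ± 106.3 to 1210 ± 44.2 CPM (edgeR adjusted p = 0.0012). Ferroptosis and iron genes had 0 of 14 higher and 2 lower, 0 and 2 adjusted over the list alone (camera adjusted p = 0.12). Autophagy and lysosome genes had 1 of 19 higher and 2 lower, 1 and 3 adjusted over the list alone (camera adjusted p = 0.41), with the cathepsin CTSL lower (edgeR adjusted p = 0.0054, 0.061 without corticosterone 2). Ribosomal protein genes (0 of 30, camera adjusted p = 0.89), nuclear oxidative phosphorylation genes (0 of 26, camera adjusted p = 0.93) and replication-dependent histone genes (0 of 13, camera adjusted p = 0.93) had no call in edgeR over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 1, 0 and 1 of them differed, and DESeq2, limma-trend and limma-voom called 0. The histones had a median log2 change of 0.02, a mean of -0.24 and a downward test.

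Both epithelial keratins and mesenchymal genes were abundant in all 6 libraries, while several luminal markers were low. KRT8 and KRT18, keratins of simple epithelia, stood at 2559 ± 114.5 and 1649 ± 128.3 CPM (n = 6), but ESR1 was at most 4.16, GATA3 at most 4.28, CDH1 at most 4.94 and EPCAM at most 4.42 CPM. VIM, the mesenchymal filament vimentin, stood at 1040 ± 32.4 CPM and CDH2, N-cadherin, at 71.1 ± 1.67 CPM (n = 6). Luminal markers had 2 of 15 higher and 0 lower, 2 and 1 adjusted over the list alone (camera adjusted p = 0.059). That p was as low as 0.021 in the fits without control 2 or corticosterone 2, and 0.019 without both control 1 and 2. KRT7, a simple-epithelial keratin, rose from 1498 ± 37.0 to 2277 ± 172.3 CPM (edgeR adjusted p = 0.00056) and the mucin MUC1 from 39.8 ± 3.54 to 60.9 ± 3.54 CPM (edgeR adjusted p = 0.0028). Basal markers passed upward in camera (adjusted p = 0.034, adjusted p = 0.30 with an estimated correlation), with 3 of 13 higher and 1 lower, 7 and 1 adjusted over the list alone. That adjusted p was 0.28 over the 9 members with at least 50 counts in 3 libraries, and up to 0.10 without control 3, corticosterone 1 or corticosterone 3. TRIM29 rose by a log2 change of 0.45 (edgeR adjusted p = 0.00068), and the keratin KRT17 fell by 0.61 on the log2 scale (edgeR adjusted p = 0.0024, and a fall by 0.53 with an adjusted p of 0.059 without both control 1 and 2).

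Epithelial-mesenchymal transition genes had 5 of 22 higher and 1 lower, 5 and 4 adjusted over the list alone, with an upward camera adjusted p of 0.39. Their median log2 change was 0.01 and their mean -0.16. SERPINE1, the plasminogen activator inhibitor, rose by a log2 change of 0.39 (edgeR adjusted p = 0.0012) and the collagen COL5A1 by 0.30 (edgeR adjusted p = 0.0020, and 0.26 with an adjusted p of 0.071 without both control 1 and 2), while the growth factor TGFB1 fell by 0.43 on the log2 scale (edgeR adjusted p = 0.0042). Wnt, Notch and stemness genes had 1 of 19 higher and 1 lower, 1 and 3 adjusted over the list alone (camera adjusted p = 0.36). Fibroblast and other cell line markers passed upward in camera (adjusted p = 0.027, adjusted p = 0.43 with an estimated correlation), with 3 of 14 higher and 0 lower, 3 and 3 adjusted over the list alone, a median log2 change of -0.15 and a mean of 0.09. Besides DCN, the proteoglycan LUM rose in that list (edgeR adjusted p = 0.010, up to 0.070 without control 1, corticosterone 1 or 2), and the list's adjusted p was up to 0.63 without control 3 or corticosterone 1. The fibrillar collagens COL3A1 and COL1A2, picked after their values were seen, varied within both groups. COL3A1 ran from 2.32 to 41.2 CPM in controls and from 0.566 to 51.6 CPM with corticosterone, and COL1A2 was at 19.7 CPM in corticosterone 1 and had no counts in corticosterone 2 and 3.

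Markers of leukocytes and endothelium were lower with corticosterone as lists, and highest in control 1 and 2. Immune cell markers fell in camera (adjusted p = 0.00042, adjusted p = 0.38 with an estimated correlation), with 0 of 11 past the threshold in edgeR and a median log2 change of -1.61. Of these, 0 were higher and 5 lower adjusted over the list alone, 6 were lower at an unadjusted p under 0.05, and DESeq2 and limma-trend called 2 each. Their summed level was 33.1 and 62.8 CPM in control 1 and 2 and between 10.50 and 23.4 CPM in the other 4 libraries, and the camera adjusted p was 0.053 without both control 1 and 2. CSF1R and CD68 did not pass (edgeR adjusted p = 0.14 and 0.16). Endothelial markers fell in camera (adjusted p = 0.041, adjusted p = 0.45 with an estimated correlation), with 1 of 7 lower and 0 higher, 1 and 0 adjusted over the list alone. That member, CDH5, fell by 0.52 on the log2 scale (edgeR adjusted p = 0.017, up to 0.082 without control 1 or any corticosterone library). The list's adjusted p was 0.052 with library size only, 0.085 over protein-coding genes only, up to 0.27 without control 2 or corticosterone 3, and 0.59 in the other direction without both control 1 and 2.

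**Figure D4:**
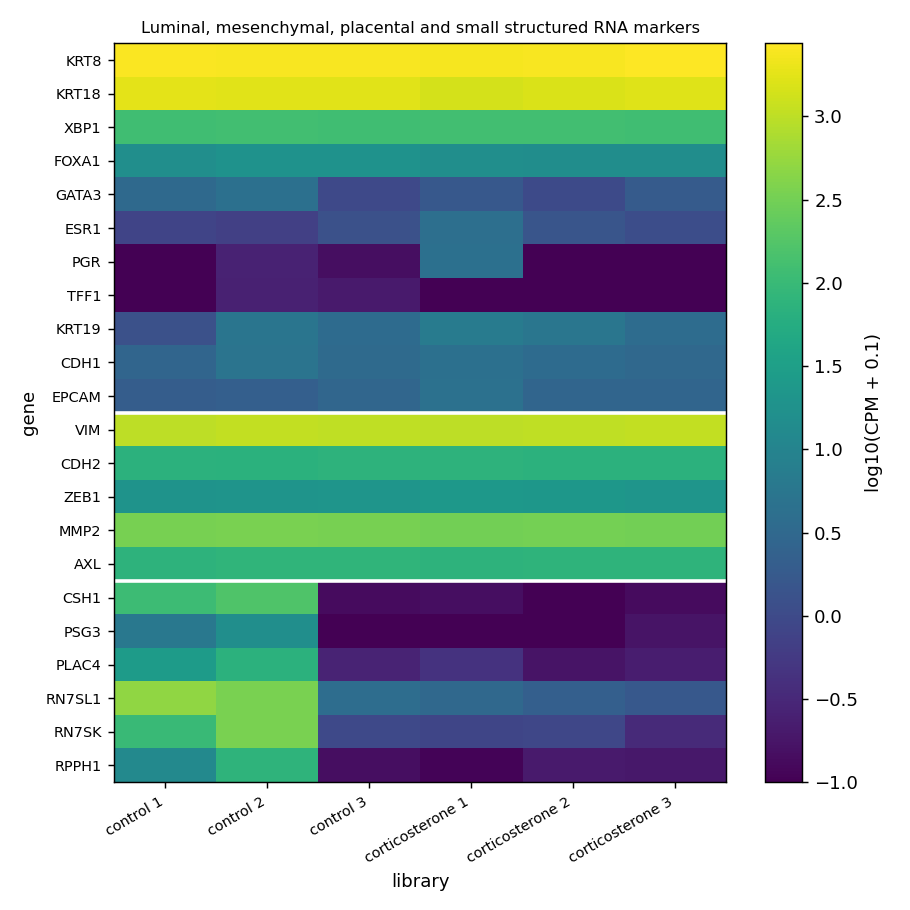
Colour gives log10(CPM + 0.1) of luminal markers (top), mesenchymal markers (middle) and placental and small structured RNA markers (bottom) in each of the 6 libraries. VIM and KRT8 averaged 1040 and 2559 CPM, and CSH1 was at 112 and 167 CPM in control 1 and 2 and at most 0.0487 CPM elsewhere.

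Among 322 KEGG terms tested with Fisher's exact test, one-sided, on 5837 background genes, none passed for the 226 called genes that rose or the 240 that fell. At an unadjusted p under 0.05 stood 19 terms of higher genes and at least 25 of lower genes. Only the 25 terms of smallest p were counted in each direction. The smallest adjusted p was 0.068 for terms of lower genes, shared by 9 terms, of which the intestinal immune network for IgA production had the smallest unadjusted p (6 of 25 genes, Fisher's exact p = 0.00042). For higher genes it was 0.35, with tyrosine metabolism first (5 of 23 genes, PNMT and MAOA among them).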

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

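The 5 tests chosen after the result was seen are the fit without control 1 and 2, the pairs alike in total count as a term, the removal of 639 genes, counts divided by 4 and the length correction. Of the 96 named genes past the threshold, DESeq2 kept 96, limma-trend 90, limma-voom 86, DESeq2 size factors and library size only 95 each, and no filter 80. The replicate block kept 63, the fit without control 1 and 2 40 and the term for pairs 33, and no kept call changed direction. DESeq2 made 17.7% false calls in simulated data with few changed genes, a share that need not hold here. Counts of genes were 1975 (915 higher, 1060 lower) with DESeq2, 366 (220, 146) at an adjusted p below 0.01 and 157 (84, 73) at a log2 change of at least 1. They were 281 (187, 94) without control 1 and 2 and 190 (128, 62) with the term for pairs, against 1038 (541, 497). The higher share, 52.1%, was 66.5% and 67.4% in the last 2. Leaving out 1 library gave 304 to 2513 genes, 191 to 1149 higher and 113 to 1364 lower, with totals of 379, 565 and 2513 without control 1, 2 and 3 and 379, 304 and 554 without corticosterone 1, 2 and 3. With an estimated correlation 1 list passed in place of 17, and leaving out 1 library gave 11 to 20 lists. With fry 12 passed. It lost p53 targets (adjusted p = 0.059), glycolysis (0.059), mitochondrially encoded (0.21) and immediate early genes (0.12) and fibroblast (0.20), immune (0.12) and endothelial markers (0.23), and gained clock genes (0.023) and luminal markers (0.036). Without a filter 21 lists passed, with the replicate block 18, and 15 each with library size only, at least 50 counts and protein-coding genes only. No filter added oestrogen receptor targets (0.023), cholesterol genes (0.047), LXR targets (0.045) and luminal markers (0.047), the block NF-kB genes (0.042), and at least 50 counts steroid and bile acid enzymes (0.017). Of the tests chosen later, 14 lists passed without control 1 and 2, 15 with the term for pairs, 19 without the 639 genes, 15 with counts divided by 4 and 17 with the length correction. Endothelial markers had too few members left to test with at least 50 counts, with counts divided by 4 and without the 639 genes. The term for pairs lost p53 targets (0.23), immediate early genes (0.27) and immune markers (0.86). Lists were not tested with DESeq2, limma-trend, limma-voom or FPKM, nor at the stricter thresholds. In the other alternatives glucocorticoid receptor targets passed upward, with adjusted p of 2.9e-79 to 1.2e-48 when 1 library was left out. The replicate number as a block gave 432 genes (250 higher, 182 lower). Deviations of same-numbered libraries from their group means correlated across genes with r of 0.07, -0.15 and 0.11. Other pairs of a control and a corticosterone library had r of -0.19 to 0.16, so same-numbered libraries were no more alike. With 3 libraries per group, whose deviations sum to 0, these values cannot exclude pairing. Pseudocount and quantile alternatives planned for FPKM as the tested unit were not run, since counts were tested. Genes under about 0.0569 CPM lay below the floor of at least 1 library.

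Lists that changed direction follow with their camera adjusted p, and the cause was not tested. Only the mitochondrially encoded genes and endothelial markers among them had passed. Without control 1 and 2, lists that turned were G2/M 0.208, oxidative phosphorylation 0.815, ribosomal proteins 0.777, NF-kB 0.755, NRF2 0.467, Wnt 0.473, histones 0.384 and endothelial markers 0.592. With the term for pairs they were steroid receptors 0.200, G2/M 0.218, mitochondrially encoded genes 0.372, NF-kB 0.321, NRF2 0.333, Wnt 0.145, histones 0.363 and endothelial markers 0.0632. Without a filter they were fatty acid 0.635, oxidative phosphorylation 0.965, ribosomal proteins 0.979, NRF2 0.965 and histones 0.979. With the length correction they were oxidative phosphorylation 0.634, ribosomal proteins 0.631, NRF2 0.947 and histones 0.644. Others were fatty acid 0.983 with the block, and histones 0.831 with at least 50 counts and 0.814 with counts divided by 4. Leaving out 1 library turned ribosomal proteins (range 0.117 to 0.961), NRF2 (0.436 to 0.967), steroid receptors (0.440 to 0.992), ATF4 (0.195 to 0.730), oxidative phosphorylation (0.187 to 0.961), steroid and bile acid enzymes (0.0358 to 0.834), histones (0.703 to 0.979) and fatty acid genes (0.690 to 0.992).

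Named genes that turned, none past the threshold, had these log2 changes. Without control 1 and 2 they were TPX2 -0.014, H1-2 -0.043, CSF1R 0.13, ZBTB16 1.75 and AR 5.95, and with the term for pairs TPX2 -0.053, MT-CO1 -0.053, MT-ND4 -0.010, RPLP0 -0.0033, H1-2 -0.12, CSF1R 0.27, ZBTB16 2.22 and AR 7.34. Both AR values depend on the prior count, as AR had no counts in control 3, so their sizes are uncertain. H1-2 was also -0.0069 with limma-voom, -0.011 with library size only, -0.000367 with at least 50 counts, -0.0012 on FPKM, -0.000205 without the 639 genes and -0.0037 with counts divided by 4. With 1 library left out, ZBTB16 ranged from -1.84 to 0.21, GREB1 from -0.23 to 0.073, ATP5F1A from -0.0171 to 0.0116 and H1-2 from -0.0737 to 0.0498.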

Other observations

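The tests of marker levels, of placental and small structured RNAs and of list changes against single controls were chosen after the result was seen, and those of other splits of the samples were set beforehand.

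Control 1 and 2 held transcripts normally made in placenta and leukocytes, and small structured RNAs. CSH1, a placental hormone, was at 112 and 167 CPM there and at most 0.0487 CPM in the other 4 libraries, PLAC4 was at 27.5 and 72.3 CPM, and PSG3 at 5.84 and 15.8 CPM. The 31 placental markers summed to 532 and 913 CPM in control 1 and 2 and to between 180 and 207 CPM elsewhere, where SVEP1 and TFPI2, which these cells also express, gave most. The 22 small structured RNAs, among them RN7SL1 and RN7SK, summed to 991 and 1510 CPM, against 5.30 to 11.1 CPM elsewhere. MMP9, a gelatinase of neutrophils and trophoblast, was at 23.0 and 45.0 CPM, against 0.752 to 3.15 CPM elsewhere. The mitochondrial ribosomal RNA MT-RNR2 was at 1756 CPM in control 2 and between 6765 and 7829 CPM in the other 5 libraries.

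The first pattern is that luminal markers were low in libraries labelled MCF-7. Of 17 luminal markers, 9 were under 10 CPM in every library, and so were 8 of 15 basal markers. The median level was 52.2 CPM in the epithelial-mesenchymal transition list, 4.33 CPM in the luminal list and 11.3 CPM over the tested genes. Summed CPM ran the other way, from 6009 to 7227 in the luminal and 5081 to 5524 in the transition list. Most of the luminal sum came from the keratins KRT8, KRT18 and KRT7, at means of 2559, 1649 and 1888 CPM (n = 6). Most of the transition sum came from FN1, VIM and COL5A1, at 1372, 1040 and 1005 CPM. Loss of reads to overlapping gene models was argued against, since 0 of the 9 low markers overlapped a same-strand gene of at least 10 CPM. The 9 were low in controls and treated libraries alike, and no explanation from the treatment was tested. The values are consistent with cells of another culture or of a changed line, which the transition list's 52.2 CPM may reflect, and a wrong label and a change of this line in culture stay open.

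The second pattern is the placental and small structured RNAs of control 1 and 2. Control 3, also untreated, held less than 0.1 of the level of both in 16 of the 24 placental markers seen there. For those 16, this argues against corticosterone as the cause of a low level in control 3. The list was written after the values were seen, so the share of 16 in 24 is no independent support. RNA or reads of another human tissue in these 2 libraries may be the source: of 18 tested immune and endothelial markers, lists fixed beforehand, 10 (55.6%) were higher in both than in each of the other 4 libraries, against 17.1% of 19926 other genes (Fisher's exact test, two-sided, p = 0.00025, across genes that are not independent). A single outside source in a fixed ratio would give a like ratio of control 2 to control 1 in every marker. That ratio ran from 0.630 in KISS1 to 10.96 in PAPPA2, a 17.4-fold spread around a median of 2.52 over 16 markers. The spread sets 2 extreme ratios against each other without their counting error, so it cannot decide for or against such a source. None of these values covered the small structured RNAs, so their source was not tested. Nor was it tested whether outside RNA entered before or after library preparation. The other 4 libraries were not alike either. Immune markers summed to 21.7 CPM in control 3 and 23.4 CPM in corticosterone 1, against 10.5 and 11.7 CPM in corticosterone 2 and 3. Endothelial markers summed to 48.6, 42.8, 43.0 and 38.7 CPM in that order. PGR and COL1A2, picked after their values were seen, were at 4.28 and 19.7 CPM in corticosterone 1. Corticosterone 2 and 3 had no counts of either.

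The third pattern is that list changes differed between the controls. The median log2 change of immediate early genes was -0.43 against control 1 and 2 and -0.10 against control 3, a ratio of 0.241, consistent with a part of that list's fall coming from a difference between control 1 and 2 and the other libraries. Such a difference as the whole source of the rise of glucocorticoid receptor targets was argued against, since against control 3 alone the median was at least 0.60 in each corticosterone library, the controls differed by at most 0.02, and 17 of the 22 members called higher stayed so without control 1 and 2. For heat shock genes, the median against control 3 was -0.14 or lower in each corticosterone library. The controls differed by at most 0.06. Without control 1 and 2 the list kept its camera call, though its members called lower lost theirs. These values argue against such a difference as the whole source of that fall, but all 3 medians share the lone control 3. Over all 6 libraries the list's camera adjusted p was 0.11 with an estimated correlation. Control 3 was the lowest control in 58.6% of genes called lower and the highest in 53.2% of genes called higher. With 3 controls alike, chance would give 33.3%. Control 3 correlated less with control 1 and 2 (Pearson r 0.976 and 0.967) than they did with each other (0.983). The shares over all tested genes were not counted, so these values cannot be read as particular to the called genes.

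Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many as 1038 genes, and the highest other gave 1 gene. For gene lists, 1 of the 10 gave as many as 17, and the highest other gave 9. The splits are too few for a share under 0.05.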
